A study of Mus musculus with 15 samples.

How the data were processed

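The series holds 15 single-cell RNA-seq libraries of tetramer-sorted splenic CD4 T cells, 11 each deficient in another transcription factor and 4 controls (3 CD4cre, 1 Prdm1flox). The authors deposited a filtered matrix per library of raw UMI counts per gene and cell barcode, not normalized. Per the submitters' processing notes these were made with Cell Ranger 7 on mm10; whether reads in introns were counted is not given in the sources. Groups and batches A to D come from the labels, which do not give the number of animals per library, so p-values measure the spread between libraries. No file maps cells to the 4 populations that the study names (1 of TFH and 3 of TR1 cells), and these were not rebuilt. Gene coordinates come from the GENCODE vM21 annotation of mm10, in which 32235 of the 32285 gene IDs were found.

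Cells with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept. A doublet caller (Scrublet in scanpy 1.11.5, expected rate 6%) marked at most 0.096% of a library, so low that the caller is taken not to have worked, and removing the 5% of cells with the highest scores per library is an alternative. Median depth per kept cell ran from 5274 to 9539 UMIs and from 2124 to 3264 genes over the libraries. Counts of the kept cells were summed per library, and counts-per-million (CPM) are relative to that sum. After a CPM value, ± is the SD over the 4 control libraries. After a log2 value, ± is an approximate standard error (SE), the absolute log2 divided by the square root of the edgeR F statistic. EdgeR gives no standard error itself, and this one was not checked against counting error. Intervals of CPM values (Poisson) and of shares (exact binomial, 95%) cover counting error only, and a share of 0 allows up to 3 cells of the total.

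Classes were built from control cells only: 2000 variable genes without the targeted, TCR, immunoglobulin, ribosomal, mitochondrial, cell cycle and sex-linked genes, centred and scaled within each batch, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2). Other cells took the majority cluster of their 15 nearest control cells, with the batch B library centred on the mean of all controls. A cluster was named "-like" from fixed markers where at least 3 were raised more than 1.5-fold and seen in at least 10% of its cells, and the mean marker score within libraries exceeded 0.3. That limit of 0.3 was not fixed beforehand, and in an earlier run of the same steps cluster 1 passed it and was called TFH-like. Shares without the limit and with 3 other clustering seeds are given as alternatives. The marker rule gave cluster 6 the name naive, but its leading genes (Lgals3, S100a4 and Vim among them) go against that name and it is given by number. Cluster 10 has a low UMI count and stays unnamed. Scaling within batches and scoring within libraries were chosen after a first clustering had been seen.

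Each deficiency was compared with the controls in edgeR 4.0.16 (R 4.3.3; TMM, filterByExpr, quasi-likelihood F test) with the 4 controls as 1 level and each deficient library as its own level. The spread thus comes from the 4 controls (3 residual degrees of freedom), and a lone library is assumed to vary like them. The same test was run on sums over TFH-like and TR1-like cells where a library had at least 50 such cells, and the difference between both classes was tested with class-by-deficiency terms and the library as a block. P-values were adjusted by Benjamini-Hochberg within a comparison (threshold 0.05). This design, the gene lists, the markers and the rule for named genes were fixed before the data were examined. The counting term (batches A and B against C and D, 2 residual degrees of freedom, 1 with a control left out) was added afterwards, and each statement that a gene rose or fell rests on it unless the sentence says otherwise. Its false-positive rate is not known: a batch A control taken out as its own level calls 133 genes, which may be differences between the CD4cre and the Prdm1flox control.

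Named genes are, per deficiency, the targeted gene, and the 6 higher and 6 lower genes with the largest absolute log2 among called genes with at least 20 CPM in either group and the same direction against each control (3 and 3 within a class). TCR, immunoglobulin, ribosomal, mitochondrial, sex-linked, Gm-numbered, Rik and accession-named genes are left out. Examples of a fixed list are its called members with the largest change, passing over any member left out of the text on request. The rule was fixed for calls without the term, and its use on calls with the term came after the data were seen. Of the genes it picks, the text gives a part, without genes of at most 3 UMIs in a group and, within classes, without markers or leading genes of the class and without globins (called under Prdm1, Bhlhe40 and Stat4), made by red cells and without an estimated background share.

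The 28 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and with fry, adjusted over all lists and deficiencies. The TFH, TR1 and Foxp3 Treg lists follow populations that the study describes and are not independent evidence of direction. Calls within 10 Mb of a targeted gene were set against calls elsewhere with Fisher's exact test. Alternatives were DESeq2 1.42.0, no expression filter, 3 CD4cre controls alone, a term for each batch, stricter cell filters (1000 genes, 2000 UMIs, 5% mitochondrial), doublets kept, classes from joint clustering or without centring, windows of 5 and 20 Mb and leaving out each control in turn. Chosen after seeing the data were the counting term, removal of barcodes that Batf shares with other libraries and of cells by doublet score, 1 spread for all batches in scaling, the other seeds, naming without the score limit, centring of Irf4 on batch A and leaving Hist1 genes out of the test near a target.

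The tests were run on simulated counts with 200 genes changed 2-, 4- or 8-fold in the place of Stat4 and Tbx21. For Stat4 in all cells (17603 genes) edgeR with the term recovered 56.7%, 91% and 100% of these, with 10 false calls among 175. Without the term edgeR recovered 0%, 0% and 0%, and DESeq2 6%, 53.7% and 72.7%. For Tbx21 edgeR with the term recovered 58.2%, 83.6% and 92.4%, with 3 false calls among 159. In TFH-like cells of Stat4 (13549 genes) edgeR without the term recovered 0%, 14.9% and 50%, and in TR1-like cells (13173 genes) 0%, 0% and 7.6%. The class-by-deficiency test recovered 13.4%, 70.3% and 86.2% (13645 genes). A planted list had a camera adjusted p of 2.15e-53, and 0 of 20 random lists were called. Random lists are no test of coexpressed lists.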

Results

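CD4 T cells were sorted by tetramer from the spleens of mice given BDC2.5/IAg7 nanoparticles, which carry a peptide on the MHC class II molecule IAg7, at 30 µg per dose on 2 occasions per week over 5 weeks. Each of the 15 libraries was profiled by 10x Chromium 3' single-cell RNA-seq, in which the unit is the unique molecular identifier (UMI) count per gene and cell. The study asked what 11 transcription factors do as T follicular helper (TFH) cells turn into type 1 regulatory (TR1) cells, which secrete the anti-inflammatory cytokine IL-10. There was 1 library per deficiency (Atf6, Batf, Bcl6, Bhlhe40, Elk4, Irf4, Maf, Prdm1, Stat3, Stat4 and Tbx21), and 4 control libraries, of which 3 were CD4cre and 1 was Prdm1flox. Per the labels, batch A held CD4cre control 1, Prdm1flox control 1, Maf, Prdm1 and Tbx21, batch B held Irf4 alone, batch C held CD4cre control 2, Bcl6, Elk4, Stat3 and Stat4, and batch D held CD4cre control 3, Atf6, Batf and Bhlhe40. Total depth in M (mega) UMIs was 47.37, 65.08 and 92.74 in CD4cre controls 1, 2 and 3 and 51.36 in the Prdm1flox control. It was 63.50 for Atf6, 58.21 for Batf, 72.29 for Bcl6, 81.16 for Bhlhe40, 88.59 for Elk4, 23.85 for Irf4, 56.55 for Maf, 67.42 for Prdm1, 68.06 for Stat3, 50.40 for Stat4 and 46.49 for Tbx21. After the cell filters 2377 (Irf4) to 8349 (Prdm1) cells remained per library. The labels do not say how many animals stand behind a library, so every spread below is a spread between libraries.

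The targeted genes were read first, in counts-per-million (CPM) of the summed UMIs, beside controls counted alike (batch A for libraries of A, batches C and D for C and D, all 4 for Irf4). Maf stood far below its controls, at 1.93 against 697 to 732 CPM. Bhlhe40 stood at 5.50 against 85.6 to 122 CPM, Tbx21 at 2.11 against 16 to 24.7, Elk4 at 30.5 against 98.0 to 104, Batf at 29.5 against 110 to 112, Prdm1 at 22.8 against 50 to 76.0 and Irf4 at 23.7 against 49.5 to 80.6. Bcl6 was not lower in the library labelled Bcl6 deficient, at 770 against 159 to 198 CPM, nor was Atf6 (42.0 against 38.7 to 41.4) or Stat3 (246 against 220 to 246), and Stat4 was slightly lower (404 against 461 to 512). The tags of this assay come from the 3' end of a transcript and can lie outside a deleted part, so these 4 values do not check the labels, and the 4 libraries are named below by label. On mm10 (GENCODE vM21) the genes lie on chromosome 1 from 170704674 to 170867771 (Atf6), 12 from 85686669 to 85709087 (Batf), 16 from 23965052 to 23988852 (Bcl6), 6 from 108660629 to 108666925 (Bhlhe40), 1 from 132007607 to 132032612 (Elk4), 13 from 30749226 to 30766976 (Irf4), 8 from 115682942 to 115707794 (Maf), 10 from 44437177 to 44528501 (Prdm1), 11 from 100885098 to 100939540 (Stat3), 1 from 51987148 to 52107189 (Stat4) and 11 from 97098071 to 97115331 (Tbx21). No p is given for a targeted gene in its own library, though it stays in the counts of called genes.

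**Figure D1:**
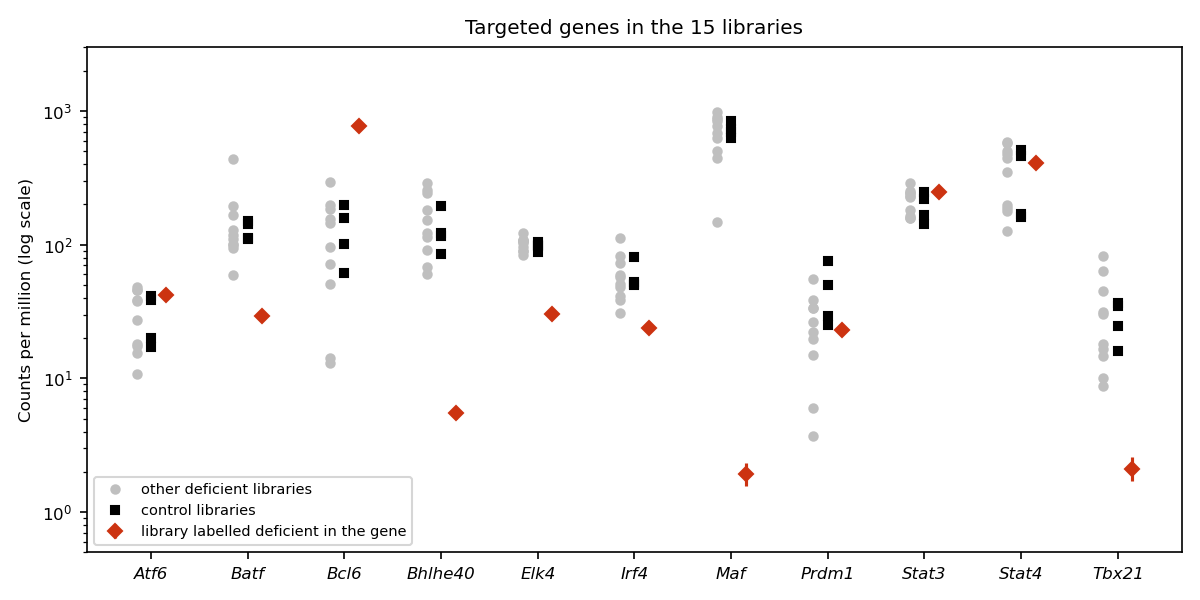
Counts-per-million (log scale) of each targeted gene in the 15 libraries: red diamonds are the library labelled deficient in that gene (bars, 95% Poisson interval), black squares the 4 controls and grey circles the other 10 deficient libraries. Maf, Bhlhe40 and Tbx21 stand at 1.93, 5.50 and 2.11 CPM in their own libraries, while Bcl6 stands at 770 CPM in its own.

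TFH-like cells, named from markers such as Cxcr5, Sostdc1 and Pdcd1, made up 7.41%, 22.8% and 26.2% of CD4cre controls 1 to 3 and 12.5% of the Prdm1flox control (mean 17.2 ± 8.77%, SD, n = 4). They were nearly missing under 4 deficiencies: 0 of 2377 cells of Irf4 (which allows up to 0.126%), 0.023% of Batf, 0.089% of Bcl6 and 0.227% of Maf, and stood at 2.73% of Stat3. The highest share was 37.2% of Elk4, above every control, and 22.2% of Atf6, 22.0% of Prdm1, 21.2% of Bhlhe40, 18.6% of Tbx21 and 17.2% of Stat4 lay inside the range of the 4 controls. That range pools batches: Prdm1 and Tbx21 lay above both batch A controls, and Atf6, Bhlhe40 and Stat4 below the control of their own batch. TR1-like cells, named from markers such as Il10, Lag3 and Havcr2, held 15.9 ± 4.17% of the controls (SD, n = 4) and lay below their range in 0.379% of Irf4, 0.527% of Prdm1, 2.83% of Batf, 7.82% of Elk4 and 8.57% of Stat3. Their shares were 18.5% of Maf, 16.3% of Bcl6, 15.7% of Atf6, 15.1% of Tbx21, 13.9% of Stat4 and 12.8% of Bhlhe40, inside that range, though Tbx21 lay below both batch A controls (21.4% and 16.9%). TR1-like cells comprised cluster 2 (led by Il10, Prdm1 and Neb), cluster 9 (Gzmb, Klrg1, Foxp3 and Ccr2) and cluster 11 (Eomes, Xcl1 and Gzmk). Cluster 11 made up 394 of 1471 TR1-like cells in Maf, 51 of 121 in Batf and 93 of 512 in Stat3, but 1 of 1011 in Tbx21, 1 of 552 in Bcl6 and 2 of 478 in Elk4, against 49 of 1575, 58 of 836 and 42 of 834 in CD4cre controls 1 to 3 and 69 of 1240 in the Prdm1flox control. Cluster 9, which scored nearly as high for Foxp3 Treg as for TR1 markers, made up 401 of 811 in Atf6, 429 of 1471 in Maf and 224 of 1011 in Tbx21, against 194, 363, 347 and 92 of those in the controls. TFH-like cells comprised cluster 4 and cluster 7, and cluster 7 held 0.204% and 0.75% of the batch A controls against 11.7% and 16% of those in C and D. Cluster 4 made up 1712 of 2273 TFH-like cells in Elk4 and 136 of 163 in Stat3, against 734 of 1508 in CD4cre control 2. Tests within either class therefore compare different mixtures of clusters. Cycling cells took 24.2% of Prdm1 against 8.82% and 8.28% of its batch A controls, and 0.234% of Stat3 against 1.89% of its batch C control. Interferon-responding cells took 4.52% of Atf6, 2.99% of Irf4 and 1.78% of Batf, against 0.272% to 0.575% of the controls. A population led by Lgals3, S100a4, Klf2 and S1pr1, called cluster 6 here, took up 68.1% of Irf4 and 55.4% of Batf cells, against 4.68% to 14.2% of the controls. Its size depends on the clustering: with seed 2 the cluster of most of the same leading genes held 823 instead of 1621 Irf4 and 1345 instead of 2370 Batf cells, and with joint clustering that led by Lgals3 and S100a4 held 6 and 12. With Irf4 centred on batch A, cluster 6 held 1104 Irf4 cells and the interferon cluster 38 instead of 71.

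Cluster 1, which carried 7 raised TFH markers but too low a mean score for a name, held 8.36%, 9.04% and 9.30% of CD4cre controls 1 to 3 and 27.5% of the Prdm1flox control. It held at most 1.12% in Stat3, Maf, Irf4, Bcl6 and Batf, and 13.7% (Atf6) to 25.7% (Prdm1) in the others. Cells of the deficient libraries took the cluster of their nearest control cells, so where class-defining genes themselves differ, as under Batf, Bcl6, Irf4, Maf and Stat3, a share counts cells that resemble control cells of the class. With all libraries clustered together the TFH-like share of Maf differed from the control mean by 40.55 percentage points instead of -17.01, so its loss of TFH-like cells rests on how classes were built. The TR1-like share of Prdm1 then differed by -7.52 instead of -15.36 points, with 501 instead of 44 such cells, so the depth of this loss does too. Shares were not tested: 1 library against 4 cannot give an exact permutation p below 0.2, one-sided.

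**Figure D2:**
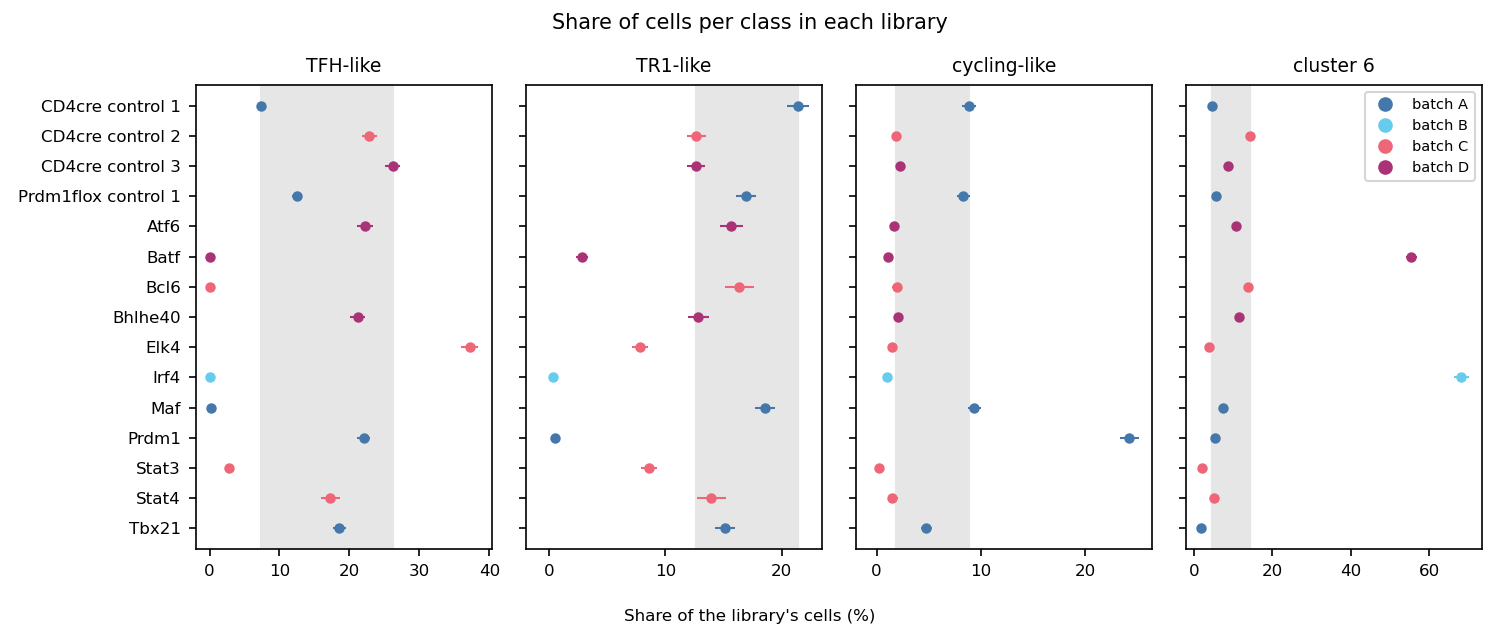
Share of each library's cells (%, horizontal axis) that fell in the TFH-like, TR1-like and cycling classes and in cluster 6, with exact 95% binomial intervals that cover counting error only; colours mark the batch and grey bands the range of the 4 controls, pooled over batches. In this clustering TFH-like cells are near 0 in Batf, Bcl6, Irf4 and Maf (for Maf not with joint clustering) and TR1-like cells in Irf4 and Prdm1, and cluster 6 fills 68.1% of Irf4 and 55.4% of Batf.

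Gene counts split the libraries by batch. Across 9693 genes, which are not independent replicates, the log2 ratio of a library to the mean of the batch A controls rose with intron length in the 9 libraries of batches C and D (Spearman rho 0.549 to 0.639). In the 6 of A and B rho was lower (-0.124 to 0.245), with a weak rise in Tbx21 (0.245) and Irf4 (0.214), while the batch A controls form the reference. Controls lay on both sides of this split, so the spread among them was wide, and the planned edgeR test on summed counts called few genes. A term for batches A and B against C and D, below the counting term, was added after this was seen. In simulated data for Tbx21 in all cells (17664 genes), the test without the term recovered 0% of genes changed 8-fold. The test with it recovered 92.4%, with 3 false calls among 159, which need not hold for real counts. A low count without the term is thus no sign of unchanged genes. Taken out as its own level, each batch A control called 133 genes with the term (1624 at an unadjusted p under 0.05) and each control of batch C or D called 0 (400 likewise). Without the term all 4 called 0, with 197, 32, 36 and 208 at an unadjusted p under 0.05 for CD4cre controls 1, 2 and 3 and the Prdm1flox control. DESeq2 called 111, 0, 1 and 133 in the same order. The 133 separate the CD4cre from the Prdm1flox control of batch A in a fit with 1 residual degree of freedom. No control was taken out within a class, so no such number stands beside the class counts. A term for each batch (1 residual degree of freedom) called 0 genes in all cells for Atf6, Bhlhe40, Elk4, Stat3 and Stat4, with 529, 504, 964, 3274 and 691 at unadjusted p under 0.05. A gene written to rise or fall below did so in edgeR's quasi-likelihood test with the counting term at a Benjamini-Hochberg adjusted p under 0.05, in the same direction against each of the 4 controls for the genes picked by size. Values are CPM in the deficient library against the mean ± SD of the 4 controls, then log2 ± SE from that fit, and counts with 1 control left out follow the order CD4cre 1, 2, 3 and Prdm1flox 1.

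**Figure D3:**
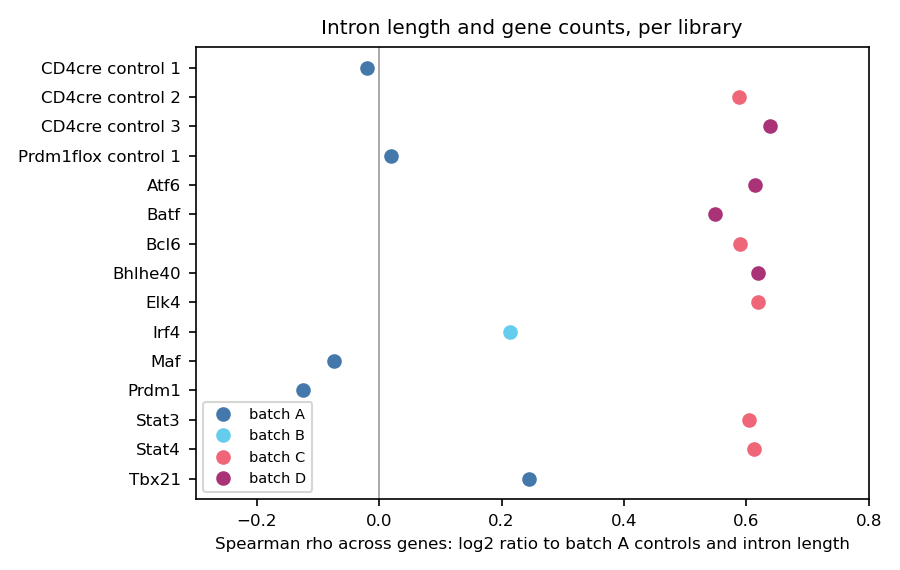
Spearman rho across 9693 genes (horizontal axis, no unit) between intron length and the log2 ratio of each library to the mean of the batch A controls, coloured by batch. The 9 libraries of batches C and D lie between 0.549 and 0.639 and the 6 of A and B between -0.124 and 0.245.

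In the library deficient in Irf4, a factor that sustains effector T cells, Il21, the cytokine of TFH cells, fell to 0.467 against 291 ± 104 CPM (log2 -9.87 ± 0.28), and the TFH-associated factor Tox2 to 0.17 against 156 ± 72.9 CPM (log2 -9.38 ± 0.79). Il7r, the IL-7 receptor, rose to 697 against 90.6 ± 54.2 CPM (log2 3.66 ± 0.22). TFH program genes, not independent evidence, fell in 13 of 25 cases and rose in 1 (14 and 1 adjusted within the list, 11 and 0 so without the term). They included Il21, Tox2 and Cebpa (log2 -7.0 ± 0.41). The TFH list was lower by camera (adjusted p = 5.21e-08, or 0.599 with estimated correlation). Among 28 TR1 program genes, not independent evidence, 17 fell and 2 rose (18 and 2 adjusted within the list, 15 and 1 so without the term). Examples were Tigit (log2 -5.96 ± 0.29), Fgl2 (log2 -5.72 ± 0.54), Ccl5 (log2 -5.41 ± 0.92) and Prdm1 (log2 -4.32 ± 0.36). The TR1 list was lower by camera (adjusted p = 1.25e-08, or 0.599 with estimated correlation). Of 14 naive and central memory genes 8 rose and 0 fell (9 and 0 adjusted within the list, 7 and 0 so without the term). These included Ly6c1 (log2 4.14 ± 0.97), Il7r and S1pr1 (log2 2.41 ± 0.11). The naive and memory list was higher by camera (adjusted p = 3.23e-08, or 0.599 with estimated correlation). Coinhibitory receptors fell in 7 of 12 cases and rose in 1 (9 and 1 adjusted within the list, 4 and 0 so without the term). Examples included Tigit, Lag3 (log2 -4.11 ± 0.54) and Havcr2 (log2 -4.03 ± 0.59). The coinhibitory list was lower by camera (adjusted p = 0.0003, or 0.599 with estimated correlation). Among 17 oxidative phosphorylation genes 17 fell and 0 rose (17 and 0 adjusted within the list, 0 and 0 so without the term). The oxidative phosphorylation list was lower by camera (adjusted p = 0.0156, or 0.743 with estimated correlation). The planned test without the term also called Ttn (135 against 3.27 ± 0.703 CPM, log2 5.27 ± 0.32 without the term), Ms4a4c (234 against 12.0 ± 1.86 CPM, log2 4.2 ± 0.23 without the term), the TFH factor Ascl2 (3.23 against 65.0 ± 10.9 CPM, log2 -4.41 ± 0.32 without the term) and Adam19 (1.15 against 72.8 ± 17.7 CPM, log2 -6.05 ± 0.41 without the term), each at an edgeR adjusted p of 0.0428. In all cells edgeR called 16 of 18504 genes without the term (0 with any 1 control left out), with 2199 at unadjusted p under 0.05, and DESeq2 called 866. The term raised this to 5820 (2435 higher, 3385 lower) by edgeR and 4131 by DESeq2, or to 5787, 4341, 4348 and 5925 with 1 control left out. Of genes named from all cells, most kept the call with any 1 control left out. Calls were lost for Ccl5 without Prdm1flox control 1 or CD4cre control 1 (adjusted p up to 0.25). Irf4 was the only library of batch B, which had no control, so genotype and batch cannot be told apart here.

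Batf is an AP-1 factor of effector T cells. In its library Sostdc1 fell to 0.746 against 90.0 ± 16 CPM (log2 -6.97 ± 0.29), Cebpa to 0.451 against 47.4 ± 12.5 CPM (log2 -6.35 ± 0.37) and Tox2 to 3.11 against 156 ± 72.9 CPM (log2 -6.03 ± 0.51). Rising genes picked by size were Mgll, a monoglyceride lipase (52.7 against 0.232 ± 0.0996 CPM, log2 7.53 ± 0.32), Tex35 (90.6 against 0.413 ± 0.154 CPM, log2 7.49 ± 0.23), Ltb4r1, a leukotriene B4 receptor (128 against 0.62 ± 0.288 CPM, log2 7.35 ± 0.32) and the sialyltransferase St6galnac1 (log2 3.27 ± 0.13). Mgll, Tex35, St6galnac1, Def8 and Sostdc1 also passed edgeR without the term, each at an adjusted p of 0.0467. Of 25 TFH program genes, not independent evidence, 14 fell and 1 rose (17 and 1 adjusted within the list, 12 and 0 so without the term). They included Sostdc1, Cebpa and Tox2. The TFH list was lower by camera (adjusted p = 4.24e-12, or 0.599 with estimated correlation). TR1 program genes, not independent evidence, fell in 6 of 28 cases and rose in 5 (8 and 5 adjusted within the list, 0 and 0 so without the term). Examples were Gzmb (log2 -5.78 ± 0.70), Tigit (log2 -4.30 ± 0.17), Eomes (log2 2.18 ± 0.14) and Prdm1 (log2 -2.09 ± 0.30). The TR1 list was lower by camera (adjusted p = 0.0182, or 0.66 with estimated correlation, and adjusted p = 0.145 with the term). Among 14 naive and central memory genes 6 rose and 0 fell (8 and 0 adjusted within the list, 3 and 0 so without the term). These included Ly6c1 (log2 4.63 ± 0.96), Igfbp4 (log2 2.91 ± 0.42) and Il7r (log2 2.28 ± 0.22). The naive and memory list was higher by camera (adjusted p = 1.44e-06, or 0.599 with estimated correlation). Of 10 Th2 genes 6 rose and 0 fell (7 and 2 adjusted within the list, 5 and 1 so without the term). Examples included Il5 (log2 6.62 ± 0.61), Il1rl1 (log2 5.15 ± 0.36) and Il13 (log2 4.78 ± 0.98). The Th2 list was higher by camera (adjusted p = 0.00244, or 0.599 with estimated correlation). Interferon-response genes rose in 12 of 17 cases and fell in 0 (13 and 0 adjusted within the list, 5 and 0 so without the term). Among them were Ifit3 (log2 2.59 ± 0.34) and Oasl2 (log2 2.13 ± 0.22). The interferon response list was higher by camera (adjusted p = 0.00278, or 0.651 with estimated correlation). Among 9 B cell genes 4 rose and 2 fell (6 and 2 adjusted within the list, 5 and 2 so without the term). They included Ighd (log2 -5.68 ± 0.52), Cd79b (log2 3.78 ± 0.28) and Iglc2 (log2 3.72 ± 0.46). The B cell list was higher by camera (adjusted p = 0.00615, or 0.599 with estimated correlation). In TR1-like cells edgeR called 12 of 13727 genes without the term (1522 at unadjusted p under 0.05, DESeq2 175). Adding the term gave 1893 (2272, 1915, 1910 and 2258 with 1 left out). There, the MHC class II gene H2-Aa (405 against 1.29 ± 0.684 CPM, log2 8.20 ± 0.58 without the term) and the factor Mef2c (40.9 against 0.172 ± 0.0666 CPM, log2 7.69 ± 0.56 without the term) were higher at an edgeR adjusted p of 0.0299 even without the term, but with any 1 control left out that test called 0 genes. Cd74, H2-Eb1 and Ighm, named after their values were seen, were also higher in that test (1050 against 12.9 ± 3.83 CPM, 455 against 6.32 ± 2.23 CPM and 5263 against 347 ± 43.4 CPM). Whether B cells or doublets were among these 121 cells was not tested. Counts in all cells were 2583 (1469 higher, 1114 lower) with the term, 3829, 661, 406 and 3830 with the term and 1 control left out, and 1643 by DESeq2 with the term. The planned test without it called 5 of 18504 (0 with any 1 control left out), had 1634 at unadjusted p under 0.05, and DESeq2 called 566. Of genes named from all cells, most kept the call with any 1 control left out. The call was lost for Il5 without CD4cre control 3 (adjusted p up to 0.0594) and for Gzmb, Igfbp4, Il13, Ly6c1, Oasl2 and Prdm1 without CD4cre control 2 or 3 (adjusted p up to 0.144). Of its barcodes 997 also occurred in CD4cre control 2, and without the shared barcodes the count with the term was 2673 and without it 18.

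In the library labelled Bcl6 deficient, for the factor that directs TFH fate, Cxcr5, the receptor that takes T cells to follicles, fell to 1.58 against 87.7 ± 22.0 CPM (log2 -5.80 ± 0.62), Cebpa to 0.277 against 47.4 ± 12.5 CPM (log2 -7.03 ± 0.38), Il4 to 0.858 against 38.9 ± 12.4 CPM (log2 -5.35 ± 0.82) and Sostdc1 to 1.49 against 90.0 ± 16 CPM (log2 -5.95 ± 0.26). Il10, the cytokine of TR1 cells, rose to 198 against 67.1 ± 40.2 CPM (log2 2.64 ± 0.15), and the IL-18 receptor gene Il18r1 to 84.1 against 7.61 ± 4.12 CPM (log2 3.01 ± 0.12). Trim16 (log2 3.02 ± 0.23), Rxra (log2 2.95 ± 0.18), Plcl1 (log2 2.77 ± 0.33) and Hdgfl3 (log2 2.52 ± 0.23) rose as well. Of 25 TFH program genes, not independent evidence, 10 fell and 3 rose (14 and 3 adjusted within the list, 8 and 2 so without the term). Examples were Cebpa, Tox2 (log2 -6.03 ± 0.51), Sostdc1 and Cxcr5. The TFH list was lower by camera (adjusted p = 2.39e-07, or 0.599 with estimated correlation). TR1 program genes, not independent evidence, rose in 6 of 28 cases and fell in 4 (7 and 5 adjusted within the list, 3 and 3 so without the term). These included Eomes (log2 -3.23 ± 0.21), Il10, Id2 (log2 2.24 ± 0.11) and Fgl2 (log2 -2.19 ± 0.31). The TR1 list was not called by camera (adjusted p = 0.123, or 0.685 with estimated correlation, and adjusted p = 0.0129 with the term). Among 12 Th1 genes 5 rose and 0 fell (5 and 0 adjusted within the list, 4 and 0 so without the term). Examples included Il18r1, Il18rap (log2 1.87 ± 0.18) and Tbx21 (log2 1.30 ± 0.23). The Th1 list was higher by camera (adjusted p = 4.43e-05, or 0.599 with estimated correlation). Of 14 naive and central memory genes 6 rose and 0 fell (8 and 0 adjusted within the list, 1 and 0 so without the term). Among them were Igfbp4 (log2 2.49 ± 0.42), Klf2 (log2 1.41 ± 0.26) and Bach2 (log2 1.37 ± 0.24). The naive and memory list was higher by camera (adjusted p = 2.69e-06, or 0.599 with estimated correlation). Within TR1-like cells edgeR called 0 of 13727 genes without the term (459 at unadjusted p under 0.05, DESeq2 14). There were 649 with the term (983, 925, 724 and 965 with 1 left out). There Plcl1 (367 against 25.0 ± 25.5 CPM, log2 2.98 ± 0.15), Def8 (log2 2.36 ± 0.24) and Epha3 (log2 2.28 ± 0.41) rose and Ntrk3 (1.60 against 21.9 ± 22.9 CPM, log2 -4.64 ± 0.69) fell. The planned edgeR test called 1 of 18504 genes in all cells, 0 with any 1 control left out, with 1267 at unadjusted p under 0.05, and DESeq2 380. With the term edgeR called 2508 (1287 higher, 1221 lower) and DESeq2 1678, and edgeR 3864, 259, 46 and 3856 with 1 control left out. Of genes named from all cells only Cebpa, Eomes, Id2, Il18r1 and Sostdc1 kept the call with any 1 control left out. Calls were lost for Hdgfl3, Il10, Klf2, Rxra, Tox2 and Trim16 without CD4cre control 3 (adjusted p up to 0.0856) and for the others without CD4cre control 2 or 3 (adjusted p up to 0.153). In TR1-like cells Epha3 lost its call without Prdm1flox control 1 or CD4cre control 1 (adjusted p up to 0.0524).

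Maf, a factor that drives Il10 and Il21 in T cells, is encoded by the gene missing here. Il21 fell to 93.6 against 291 ± 104 CPM (log2 -1.90 ± 0.16) and Il10 to 38.8 against 67.1 ± 40.2 CPM (log2 -1.26 ± 0.17). Ascl2, which directs TFH cells to follicles, fell to 1.52 against 65.0 ± 10.9 CPM (log2 -5.13 ± 0.22), Sccpdh to 1.98 against 54.0 ± 6.98 CPM (log2 -4.64 ± 0.25) and Cebpa to 5.70 against 47.4 ± 12.5 CPM (log2 -3.19 ± 0.27). Carbonic anhydrase Car2 rose to 62.9 against 2.86 ± 0.92 CPM (log2 4.82 ± 0.33), the chemokine Xcl1 to 47.3 against 3.39 ± 0.703 CPM (log2 3.84 ± 0.23) and the costimulatory receptor Tnfrsf9 to 71.2 against 14.3 ± 5.03 CPM (log2 2.89 ± 0.30). Cytotoxic and chemokine genes rose in 5 of 14 cases and fell in 0 (14 and 0 adjusted within the list, 14 and 0 so without the term). They included Klrd1 (log2 4.78 ± 0.49), Xcl1, Klrk1 (log2 3.43 ± 0.68) and Prf1 (log2 2.92 ± 0.38). The cytotoxic and chemokine list was higher by camera (adjusted p = 9.22e-24, or 0.599 with estimated correlation). Among 25 TFH program genes, not independent evidence, 5 fell and 1 rose (14 and 2 adjusted within the list, 11 and 2 so without the term). Examples were Ascl2, Cebpa and Il21. The TFH list was lower by camera (adjusted p = 2.69e-07, or 0.599 with estimated correlation). Of 28 TR1 program genes, not independent evidence, 6 fell and 3 rose (7 and 13 adjusted within the list, 2 and 8 so without the term). These included Eomes (log2 2.24 ± 0.13), Ccr2 (log2 -1.52 ± 0.11), Id2 (log2 1.38 ± 0.11) and Il10. The TR1 list was higher by camera (adjusted p = 0.00278, or 0.64 with estimated correlation, and adjusted p = 0.128 with the term). Foxp3 Treg program genes, not independent evidence, rose in 6 of 16 cases and fell in 1 (10 and 2 adjusted within the list, 4 and 1 so without the term). Examples included Lrrc32 (log2 4.23 ± 0.82), Itgae (log2 3.72 ± 0.45) and Il1rl1 (log2 3.51 ± 0.38). The Foxp3 Treg list was higher by camera (adjusted p = 1.82e-06, or 0.599 with estimated correlation). Among TR1-like cells edgeR called 3 of 13727 genes without the term (647 at unadjusted p under 0.05, DESeq2 75). This became 1324 with the term (1277, 1683, 1688 and 1337 with 1 left out). St6galnac1 (0.482 against 25.9 ± 1.87 CPM, log2 -5.50 ± 0.34 without the term) was lower there without the term, at an edgeR adjusted p of 0.0471, but that test called 0 genes with any 1 control left out or with cells clustered jointly. In all cells edgeR called 0 of 18504 genes without the term, with 978 at unadjusted p under 0.05, and DESeq2 called 299. The term raised this to 806 (460 higher, 346 lower) by edgeR and 856 by DESeq2, or to 1999, 29, 29 and 1049 with 1 control left out. Of genes named from all cells only Ascl2, Car2, Eomes, Klrd1 and Sccpdh kept the call with any 1 control left out. It was lost for Ccr2, Cebpa, Id2, Il10, Il1rl1, Il21, Itgae, Klrk1, Lrrc32, Prf1, Tnfrsf9 and Xcl1 without CD4cre control 2 or 3 (adjusted p up to 0.14).

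Prdm1, which encodes Blimp-1, a driver of Il10 in effector T cells, was taken out in 1 library. There Il10 fell to 3.71 against 67.1 ± 40.2 CPM (log2 -4.65 ± 0.21), the chemokine receptor Ccr2 to 2.43 against 21.3 ± 0.912 CPM (log2 -3.07 ± 0.13) and Neb to 0.734 against 24.8 ± 2.96 CPM (log2 -5.01 ± 0.23). The antiviral membrane gene Ifitm1 rose to 40.9 against 0.195 ± 0.202 CPM (log2 8.70 ± 0.92), and Lgals3 (log2 2.47 ± 0.26), the decoy receptor Il1r2 (log2 2.77 ± 0.43) and the histone gene Hist1h1b (log2 2.83 ± 0.18) rose too. Among 28 TR1 program genes, not independent evidence, 9 fell and 1 rose (13 and 1 adjusted within the list, 6 and 1 so without the term). Among them were Gzmb (log2 -6.91 ± 0.92), Il10, Havcr2 (log2 -3.31 ± 0.49) and Ccr2. The TR1 list was lower by camera (adjusted p = 1.06e-05, or 0.599 with estimated correlation). Of 25 TFH program genes, not independent evidence, 6 rose and 1 fell (7 and 1 adjusted within the list, 3 and 0 so without the term). They included Sh2d1a (log2 1.34 ± 0.15), Sostdc1 (log2 1.19 ± 0.17), Cxcr4 (log2 1.17 ± 0.17) and Cebpa (log2 1.16 ± 0.21). The TFH list was higher by camera (adjusted p = 0.00183, or 0.599 with estimated correlation). Cell cycle genes rose in 9 of 18 cases and fell in 0 (18 and 0 adjusted within the list, 0 and 0 so without the term). Examples were Ccnb2 (log2 2.71 ± 0.37), Ube2c (log2 2.60 ± 0.29) and Cenpf (log2 2.07 ± 0.34). The cell cycle list was higher by camera (adjusted p = 5.21e-08, or 0.599 with estimated correlation). Without the term Ccnb2 and Ube2c had the opposite sign (log2 -0.88 and -0.57, not called), since controls outside batch A stood higher (up to 15.9 and 21.1 CPM). Among 14 glycolysis and hypoxia genes 7 rose and 0 fell (9 and 0 adjusted within the list, 0 and 0 so without the term). These included Tpi1 (log2 1.65 ± 0.09), Hk2 (log2 1.63 ± 0.26) and Pgam1 (log2 0.88 ± 0.09). The glycolysis and hypoxia list was higher by camera (adjusted p = 3.55e-06, or 0.599 with estimated correlation). Of 9 Th17 genes 4 rose and 0 fell (6 and 0 adjusted within the list, 5 and 0 so without the term). Examples included Il23r (log2 6.37 ± 0.97) and Ccr6 (log2 3.44 ± 0.51). The Th17 list was higher by camera (adjusted p = 0.000786, or 0.599 with estimated correlation). In TFH-like cells edgeR called 0 of 13742 genes without the term (272 at unadjusted p under 0.05, DESeq2 9). In total 59 passed with the term (233, 186, 193 and 111 with 1 left out). There Ccdc28b (117 against 30.2 ± 10.7 CPM, log2 1.64 ± 0.15) rose and Gal (the neuropeptide galanin, 25.2 against 96.0 ± 12.6 CPM, log2 -1.90 ± 0.16), Dhrs3 (log2 -1.48 ± 0.15) and Tnfrsf14 (log2 -1.07 ± 0.19) fell. Counts in all cells were 806 (599 higher, 207 lower) with the term, 1222, 3, 3 and 1281 with the term and 1 control left out, and 630 by DESeq2 with the term. The planned test without it called 0 of 18504, had 639 at unadjusted p under 0.05, and DESeq2 called 88. Of genes named from all cells only Ccr2 kept the call with any 1 control left out. The call was lost for Ifitm1 with any 1 control left out (adjusted p up to 0.161) and for the others without CD4cre control 2 or 3 (adjusted p up to 0.161).

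In the library labelled Stat3 deficient, for the transducer of IL-6 and IL-21 signals, Socs3, the feedback inhibitor of cytokine signals, fell to 3.37 against 37.9 ± 11.2 CPM (log2 -3.26 ± 0.51). STAT3 targets fell in 4 of 15 cases and rose in 1 (7 and 1 adjusted within the list, 2 and 0 so without the term). Among them were Socs3, Bcl3 (log2 -1.47 ± 0.11), Il10 (log2 1.14 ± 0.15) and Batf (log2 -0.97 ± 0.10). The STAT3 target list was lower by camera (adjusted p = 0.000574, or 0.64 with estimated correlation). Tox2 fell to 24.5 against 156 ± 72.9 CPM (log2 -3.19 ± 0.42) and Cebpa to 5.63 against 47.4 ± 12.5 CPM (log2 -2.85 ± 0.26). Tanc2, which lies 4.65 Mb from Stat3 and may carry a strain allele, rose to 151 against 4.99 ± 4.53 CPM (log2 4.03 ± 0.15), Car2 to 40.9 against 2.86 ± 0.92 CPM (log2 3.58 ± 0.31), and Il10 to 77.2 against 67.1 ± 40.2 CPM (log2 1.14 ± 0.15). Without the term Il10 was not called there (log2 -0.07). Among 25 TFH program genes, not independent evidence, 8 fell and 0 rose (11 and 1 adjusted within the list, 6 and 0 so without the term). They included Tox2, Cebpa and Sostdc1 (log2 -2.57 ± 0.21). The TFH list was lower by camera (adjusted p = 7.04e-07, or 0.599 with estimated correlation). Of 18 cell cycle genes 8 fell and 0 rose (14 and 0 adjusted within the list, 0 and 0 so without the term). Examples were Rrm2 (log2 -2.23 ± 0.41), Ube2c (log2 -2.21 ± 0.28) and Ccnb2 (log2 -2.18 ± 0.33). The cell cycle list was lower by camera (adjusted p = 7.95e-06, or 0.599 with estimated correlation). Within TFH-like cells edgeR called 0 of 13742 genes without the term (1073 at unadjusted p under 0.05, DESeq2 29). The term brought this to 585 (1045, 789, 745 and 1099 with 1 left out). There Ins2 (insulin, 32.2 against 0.264 ± 0.306 CPM, log2 5.83 ± 0.60), C3 (complement C3, log2 5.12 ± 0.44) and Sash1 (log2 5.10 ± 0.55) rose and Emp3 (5.63 against 75.7 ± 29.8 CPM, log2 -4.21 ± 0.37), Gal (log2 -3.90 ± 0.35) and Vim (log2 -3.03 ± 0.59) fell. In TR1-like cells edgeR called 0 of 13727 genes without the term (573 at unadjusted p under 0.05, DESeq2 15). Adding the term gave 939 (1322, 1180, 913 and 1314 with 1 left out). There Tanc2 (136 against 5.89 ± 5.41 CPM, log2 3.65 ± 0.20), Ntn4 (log2 3.53 ± 0.23) and Col24a1 (log2 3.51 ± 0.42) rose and Socs3 (9.34 against 72.8 ± 12.3 CPM, log2 -2.87 ± 0.29) and Metrnl (log2 -2.77 ± 0.30) fell. The planned edgeR test called 0 of 18504 genes in all cells with 984 at unadjusted p under 0.05, and DESeq2 177. With the term edgeR called 1588 (648 higher, 940 lower) and DESeq2 1302, and edgeR 3095, 0, 0 and 3089 with 1 control left out. Of genes named from all cells, Socs3 lost its call with any 1 control left out (adjusted p up to 0.193). The others lost it without CD4cre control 2 or 3 (adjusted p up to 0.175).

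Tbx21 encodes T-bet, the factor of Th1 cells. Cxcr3, a chemokine receptor that T-bet activates, fell to 0.522 against 144 ± 28.3 CPM (log2 -8.08 ± 0.42). Serpina9 (log2 -4.15 ± 0.19), Cd22 (log2 -2.74 ± 0.16) and Sorl1 (log2 -2.64 ± 0.18) fell too. Amphiregulin (Areg) rose to 41.7 against 6.47 ± 0.513 CPM (log2 2.52 ± 0.13) and the signalling regulator Rgs2 to 96.4 against 22.8 ± 9.04 CPM (log2 1.55 ± 0.14). Th17 genes rose in 4 of 9 cases and fell in 0 (9 and 0 adjusted within the list, 7 and 0 so without the term). These included Il23r (log2 7.15 ± 0.92), Il17f (log2 5.83 ± 0.64) and Ccr6 (log2 5.22 ± 0.50). The Th17 list was higher by camera (adjusted p = 5.18e-21, or 0.599 with estimated correlation). Among 10 Th2 genes 5 rose and 0 fell (8 and 0 adjusted within the list, 6 and 0 so without the term). Examples included Il13 (log2 7.75 ± 0.72), Il5 (log2 5.81 ± 0.74) and Il1rl1 (log2 4.32 ± 0.38). The Th2 list was higher by camera (adjusted p = 3.97e-15, or 0.599 with estimated correlation). Of 12 Th1 genes 2 fell and 0 rose (3 and 2 adjusted within the list, 3 and 0 so without the term). Among them was Cxcr3. The Th1 list was lower by camera (adjusted p = 2.09e-05, or 0.599 with estimated correlation). Cytotoxic and chemokine genes fell in 1 of 14 cases and rose in 0 (8 and 1 adjusted within the list, 7 and 1 so without the term). This was Xcl1 (log2 -4.46 ± 0.44). The cytotoxic and chemokine list was lower by camera (adjusted p = 1.7e-09, or 0.599 with estimated correlation). Among TFH-like cells edgeR called 0 of 13742 genes without the term (347 at unadjusted p under 0.05, DESeq2 15). There were 175 with the term (469, 429, 427 and 263 with 1 left out). There Klrb1a (23.2 against 5.91 ± 2.28 CPM, log2 2.44 ± 0.35), Tmem14c (log2 1.84 ± 0.14) and Shtn1 (log2 1.72 ± 0.17) rose and Serpina9 (1.97 against 37.1 ± 5.79 CPM, log2 -4.39 ± 0.28), Sorl1 (log2 -3.14 ± 0.20) and Cd22 (log2 -2.38 ± 0.15) fell. Within TR1-like cells edgeR called 0 of 13727 genes without the term (406 at unadjusted p under 0.05, DESeq2 38). This became 607 with the term (710, 897, 895 and 596 with 1 left out). There Ccr6 (a Th17 chemokine receptor, 36.6 against 1.04 ± 0.708 CPM, log2 6.04 ± 0.42) and Il1rl1 (the IL-33 receptor, log2 5.79 ± 0.27) rose. In all cells edgeR called 0 of 18504 genes without the term, with 416 at unadjusted p under 0.05, and DESeq2 called 76. The term gave 129 (88 higher, 41 lower) by edgeR and 287 by DESeq2, or 521, 1, 1 and 516 with 1 control left out. The 133 of a batch A control rest on the spread behind 521 and 516, not 129. All genes named from all cells lost the call without CD4cre control 2 or 3 (adjusted p up to 0.214).

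Atf6 encodes a sensor of stress in the endoplasmic reticulum, and the library labelled Atf6 deficient had raised interferon genes. Ifi213 rose to 52.9 against 0.284 ± 0.153 CPM (log2 8.33 ± 0.27), Ifi206 to 79.9 against 2.45 ± 1.43 CPM (log2 4.45 ± 0.25) and Oasl2, an antiviral gene, to 24.3 against 1.94 ± 0.309 CPM (log2 3.64 ± 0.22). Ifi213 and Ifi206 lie 2.70 and 2.60 Mb from Atf6 and may carry a strain allele. Among 17 interferon-response genes 10 rose and 0 fell (14 and 0 adjusted within the list, 8 and 0 so without the term). Examples were Ifit3 (log2 4.03 ± 0.34), Oasl2, Rsad2 (log2 3.38 ± 0.18) and Ifit1 (log2 2.80 ± 0.14). The interferon response list was higher by camera (adjusted p = 2e-15, or 0.599 with estimated correlation). The 18 genes of ER stress and the unfolded protein response held 0 calls (0 also adjusted within the list, with or without the term). The ER stress list was lower by camera (adjusted p = 0.000919, or 0.66 with estimated correlation, and adjusted p = 0.217 with the term). Def8 rose to 63.5 against 5.72 ± 0.192 CPM (log2 3.42 ± 0.11) and Hopx to 32.9 against 4.01 ± 0.684 CPM (log2 2.81 ± 0.16). In TFH-like cells edgeR called 0 of 13742 genes without the term (125 at unadjusted p under 0.05, DESeq2 3). In total 55 passed with the term (143, 117, 114 and 159 with 1 left out). There Ifi213 (26.5 against 0.239 ± 0.366 CPM, log2 8.12 ± 0.60), Ifi206 (log2 4.12 ± 0.35) and Def8 (log2 3.66 ± 0.19) rose and Gal (37.2 against 96.0 ± 12.6 CPM, log2 -1.30 ± 0.15), Chn1 (log2 -0.89 ± 0.15) and Nrn1 (neuritin, log2 -0.86 ± 0.13) fell. Among TR1-like cells edgeR called 0 of 13727 genes without the term (138 at unadjusted p under 0.05, DESeq2 2). The term brought this to 99 (179, 182, 244 and 179 with 1 left out). Counts in all cells were 40 (38 higher, 2 lower) with the term, 133, 0, 0 and 132 with the term and 1 control left out, and 62 by DESeq2 with the term. The planned test without it called 0 of 18504, had 165 at unadjusted p under 0.05, and DESeq2 called 20. Of genes named from all cells, Ifit3 lost its call with any 1 control left out (adjusted p up to 0.193). The others lost it without CD4cre control 2 or 3 (adjusted p up to 0.251).

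Few genes passed under Bhlhe40 deficiency, which removes a regulator of T cell cytokines. Trim12a rose to 36.4 against 0.552 ± 0.243 CPM (log2 6.72 ± 0.26) and Cdk5rap1 to 81.1 against 9.49 ± 2.48 CPM (log2 2.82 ± 0.11). Of 28 TR1 program genes, not independent evidence, 0 passed (fell, then rose: 2 and 0 adjusted within the list, 0 and 0 so without the term). By camera the TR1 list was lower (adjusted p = 0.000241, or 0.599 with estimated correlation). The 7 erythroid and platelet genes (of cells outside the sort) held 0 calls (rose, then fell: 5 and 0 adjusted within the list, 4 and 0 so without the term). The erythroid and platelet list was higher by camera (adjusted p = 2.72e-10, or 0.599 with estimated correlation). Within TFH-like cells edgeR called 0 of 13742 genes without the term (124 at unadjusted p under 0.05, DESeq2 9). Adding the term gave 60 (206, 129, 163 and 222 with 1 left out). There Trim12a (30.6 against 0.6 ± 0.487 CPM, log2 7.16 ± 0.42) and Cdk5rap1 (log2 3.07 ± 0.16) rose and Cd4 (the sorting antigen, 344 against 922 ± 604 CPM, log2 -2.05 ± 0.12) and Thy1 (log2 -1.0 ± 0.16) fell. In TR1-like cells edgeR called 0 of 13727 genes without the term (129 at unadjusted p under 0.05, DESeq2 4). There were 63 with the term (142, 150, 234 and 137 with 1 left out). There Trim12a (24.4 against 0.744 ± 0.392 CPM, log2 5.76 ± 0.49) and Cdk5rap1 (log2 2.65 ± 0.18) rose and Cd4 (337 against 894 ± 454 CPM, log2 -1.90 ± 0.15) and Fosb (an AP-1 gene, log2 -0.81 ± 0.14) fell. The planned edgeR test called 0 of 18504 genes in all cells with 159 at unadjusted p under 0.05, and DESeq2 16. With the term edgeR called 10 (7 higher, 3 lower) and DESeq2 41, and edgeR 169, 0, 0 and 169 with 1 control left out. Each gene named from all cells lost its call without CD4cre control 2 or 3 (adjusted p up to 0.167).

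Elk4 is a ternary complex factor that works with SRF. In its library Mfsd4a fell to 2.29 against 27.9 ± 1.85 CPM (log2 -3.66 ± 0.16), Ramp1, part of the CGRP receptor, to 95.2 against 257 ± 37.6 CPM (log2 -1.63 ± 0.12), and Ccr2 to 9.67 against 21.3 ± 0.912 CPM (log2 -1.14 ± 0.11). Rnpep rose to 49.6 against 20.4 ± 1.27 CPM (log2 1.19 ± 0.11). Of 28 TR1 program genes, not independent evidence, 2 fell and 0 rose (5 and 2 adjusted within the list, 0 and 0 so without the term). They included Eomes (log2 -3.61 ± 0.20) and Ccr2. By camera the TR1 list was lower (adjusted p = 4.88e-07, or 0.599 with estimated correlation). The 15 targets of SRF and ternary complex factors held 0 calls (fell, then rose: 1 and 1 adjusted within the list, 0 and 0 so without the term). The SRF target list was lower by camera (adjusted p = 0.00186, or 0.66 with estimated correlation, and adjusted p = 0.259 with the term). Among TFH-like cells edgeR called 0 of 13742 genes without the term (217 at unadjusted p under 0.05, DESeq2 7). This became 245 with the term (610, 337, 319 and 656 with 1 left out). There Whrn (27.5 against 7.76 ± 2.46 CPM, log2 1.46 ± 0.19), Rnpep (log2 1.28 ± 0.14) and Airn (log2 1.24 ± 0.16) rose and Mfsd4a (3.67 against 38.6 ± 6.04 CPM, log2 -3.33 ± 0.20), Il7r (the IL-7 receptor, log2 -2.14 ± 0.18) and Ramp1 (part of the CGRP receptor, log2 -1.60 ± 0.12) fell. Within TR1-like cells edgeR called 0 of 13727 genes without the term (167 at unadjusted p under 0.05, DESeq2 3). In total 69 passed with the term (141, 189, 197 and 141 with 1 left out). There Swap70 (26.4 against 7.44 ± 1.88 CPM, log2 1.56 ± 0.22), Casc4 (log2 1.28 ± 0.25) and Fkbp5 (a glucocorticoid-induced gene, log2 1.16 ± 0.10) rose and Cyth3 (18.6 against 38.9 ± 7.38 CPM, log2 -1.25 ± 0.21) and Hist1h1e (log2 -0.77 ± 0.16) fell. In all cells edgeR called 0 of 18504 genes without the term, with 233 at unadjusted p under 0.05, and DESeq2 called 15. The term raised this to 24 (8 higher, 16 lower) by edgeR and 80 by DESeq2, or to 451, 0, 0 and 451 with 1 control left out. All genes named from all cells lost the call without CD4cre control 2 or 3 (adjusted p up to 0.587).

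The library labelled Stat4 deficient, for the transducer of IL-12 signals, differed from the controls in few genes. The calcium-binding gene S100a11 rose to 214 against 91.2 ± 7.15 CPM (log2 1.18 ± 0.11) and Dnah8 to 163 against 39.4 ± 28.1 CPM (log2 1.36 ± 0.10). Dst fell to 52.0 against 106 ± 36.0 CPM (log2 -1.38 ± 0.13). Among 12 Th1 genes 1 fell and 0 rose (3 and 0 adjusted within the list, 0 and 0 so without the term). This was Il18r1 (log2 -1.50 ± 0.15). The Th1 list was not called by camera (adjusted p = 0.339, or 0.746 with estimated correlation, and adjusted p = 0.00979 with the term). In TFH-like cells edgeR called 0 of 13742 genes without the term (255 at unadjusted p under 0.05, DESeq2 6). The term brought this to 41 (180, 188, 127 and 201 with 1 left out). There S100a11 (398 against 73.0 ± 10.5 CPM, log2 2.26 ± 0.11), Fgf13 (log2 1.24 ± 0.14) and Cers6 (log2 1.08 ± 0.16) rose and Cd4 (341 against 922 ± 604 CPM, log2 -2.10 ± 0.12), Gal (log2 -1.64 ± 0.18) and Bmpr2 (log2 -1.44 ± 0.19) fell. Among TR1-like cells edgeR called 0 of 13727 genes without the term (222 at unadjusted p under 0.05, DESeq2 1). Adding the term gave 97 (276, 365, 192 and 270 with 1 left out). There Camk2b (30.1 against 2.75 ± 3.08 CPM, log2 2.58 ± 0.32) and Plcl1 (log2 1.59 ± 0.16) rose and Fabp5 (a fatty acid-binding protein, 7.46 against 37.0 ± 12.5 CPM, log2 -1.82 ± 0.25), Cd4 (log2 -1.81 ± 0.15) and Hopx (log2 -1.68 ± 0.24) fell. Counts in all cells were 12 (5 higher, 7 lower) with the term, 170, 0, 0 and 170 with the term and 1 control left out, and 55 by DESeq2 with the term. The planned test without it called 0 of 18504, had 181 at unadjusted p under 0.05, and DESeq2 called 3. Each gene named from all cells lost its call without CD4cre control 2 or 3 (adjusted p up to 0.894).

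**Figure D4:**
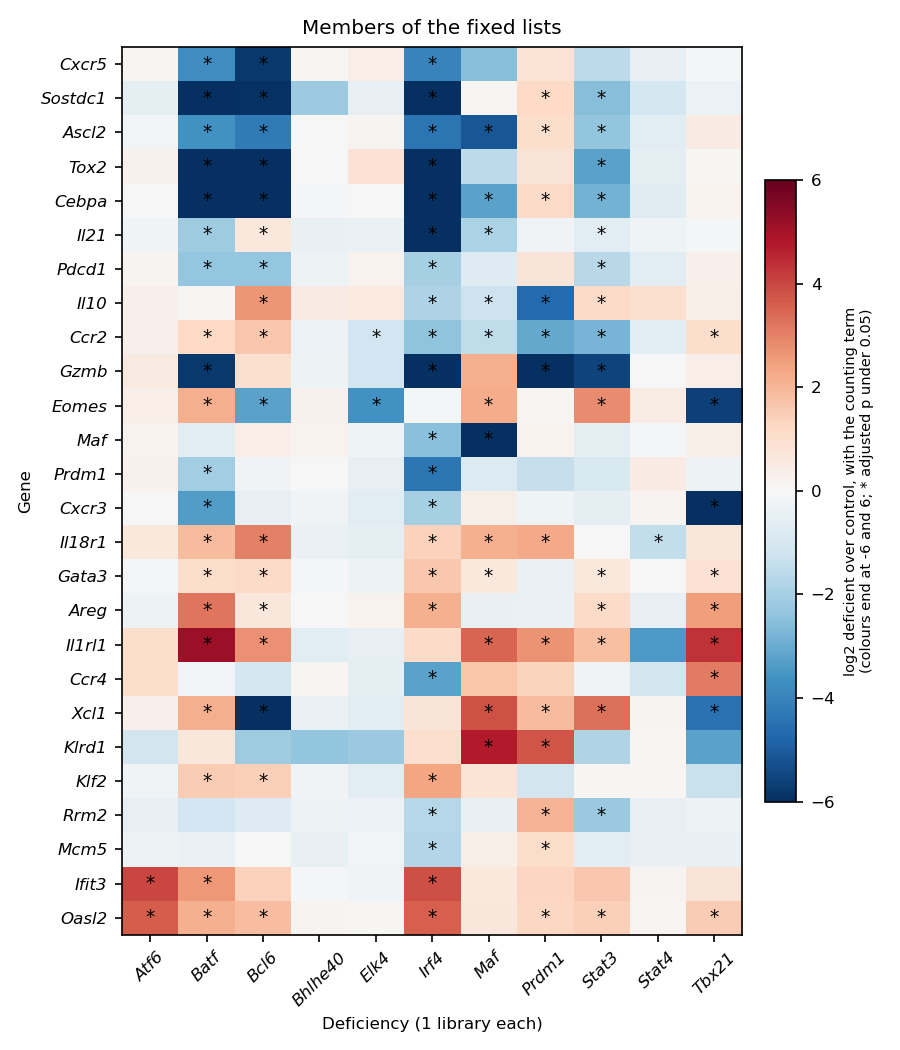
Log2 ratio of each deficient library to the controls with the counting term (colour, ending at -6 and 6) for 26 genes (vertical axis) under the 11 deficiencies (horizontal axis); asterisks mark a Benjamini-Hochberg adjusted edgeR p under 0.05. Among the TFH genes at the top, Tox2 stands at -9.38, -6.03 and -6.03 in Irf4, Batf and Bcl6, and Il10 is lowest in Prdm1 at -4.65.

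Without the term, TFH program members called over all genes by edgeR numbered 1 under Batf and 2 under Irf4. Over the 11 deficiencies and 28 fixed lists, camera with a preset correlation called 144 of 308 tests without the term and 135 with it, and 101 were called both ways in the same direction. With an estimated correlation none passed (0 of 308, smallest adjusted p 0.599 without the term and 0.66 with it), nor did any by fry (smallest 0.143 and 0.124). Whether a change differed between TR1-like and TFH-like cells was tested with class-by-deficiency terms in the 6 deficiencies with both classes. Under Tbx21 deficiency edgeR called 13 of 14099 genes, among them Areg 2.01 ± 0.27, Cd69 1.58 ± 0.24, Il4 2.40 ± 0.27 and Il7r 2.94 ± 0.27 (log2 change in TR1-like minus that in TFH-like cells ± SE), and Nr4a2 -3.39 ± 0.38, Bach2 -1.92 ± 0.28, Ctsw -4.43 ± 0.54 and Foxp3 -2.26 ± 0.33 with the opposite sign. Under Stat3 deficiency edgeR called 5 of 14099 genes, named here after their values were seen as Sntb2 2.14 ± 0.31 and Il7r 2.32 ± 0.33, and Atp1b1 -4.36 ± 0.52, BC018473 -3.36 ± 0.28 and Vdr -1.96 ± 0.28 with the opposite sign. These signs compare changes and not levels: under Tbx21 deficiency Il4 stood at 110 against 9.85 CPM in TR1-like and 264 against 122 CPM in TFH-like cells, and Foxp3 at 119 against 74.7 CPM in TR1-like and 9.85 against 1.17 CPM in TFH-like cells. Foxp3 leads cluster 9, so its difference may follow the mixture of clusters. EdgeR called 0 genes for Atf6, Bhlhe40, Elk4 and Stat4, with 398, 356, 397 and 572 at unadjusted p under 0.05, and no other tool was run for this test.

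Genes close to a targeted locus can carry alleles of the strain in which the locus was altered, and calls near each target were compared with calls elsewhere by two-sided Fisher's exact test, adjusted over the 11 deficiencies. Within 10 Mb of Atf6, 4 of 207 tested genes were called with the counting term (odds ratio 9.99, adjusted p = 0.00559), among them the interferon-inducible Ifi206, Ifi213 and Ifi204 at 2.60, 2.70 and 2.88 Mb. Near Elk4, 2 of 140 were called (odds ratio 12.7, adjusted p = 0.0476), of which Mfsd4a overlaps it and Rnpep lay at 3.23 Mb. Near Irf4, 91 of 176 were called (odds ratio 2.35, adjusted p = 3.07e-07). Of these, 37 were Hist1 genes of 1 histone cluster, all higher, which the test takes as independent. With Hist1 genes left out, 54 of 126 were called (odds ratio 1.65, adjusted p = 0.0372). Without the term 1 of 176 was called near Irf4 and 0 near each other target. Atf6 and Elk4 had 0 such calls anywhere and Irf4 had 16 in all, too few to tell of an excess.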

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

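Tests chosen only after the result was seen are those of intron counting, of depth, of genotype between batches, of strain differences and of Hist1 genes near a target, and of a strain variant or a transgene behind Cd4.

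Irf4 stood at 80.6 CPM in CD4cre control 1 and at 49.5 to 52.1 CPM in the other 3 controls, a large gap for a group of 4. It was the only case in 18 groups of control values, and chance gives about 1 in 20.

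Under Tbx21 deficiency the change differed between TR1-like and TFH-like cells for 13 genes by edgeR's class-by-deficiency test. The log2 change in TR1-like cells minus that in TFH-like cells was 2.94 for Il7r, 2.40 for Il4, 2.01 for Areg and 1.58 for Cd69. It was -4.43 for Ctsw, -3.39 for Nr4a2, -2.26 for Foxp3 and -1.92 for Bach2. Under Stat3 deficiency 5 genes differed, Il7r by 2.32. No explanation was tested for these.

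Genes with long introns had more counts in batches C and D than in batch A, in deficient libraries and controls alike. Total depth is argued against, since Atf6, inside the range of A and B, still had a rho of 0.614. A difference in genotype is argued against as well, since CD4cre controls 2 and 3 had a rho of at least 0.588 against controls that include CD4cre control 1. Reads in introns that were counted in C and D and not in A and B could give this pattern, with a rho of at least 0.549 in each of those 9 libraries, but it leaves the weaker rise in Tbx21 (0.245) and Irf4 (0.214) unexplained. Median depth per cell, lower in all of A and B, and other differences in library preparation stay open, and no biological explanation was tested.

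Called genes gathered within 10 Mb of the target in 3 deficiencies (Atf6, Elk4 and Irf4) with the counting term. Of these 97 genes 9 (9.28%) lay within 1 Mb, near what an even spread over 10 Mb gives. An effect of the deletion on adjacent genes thus stays open, and Mfsd4a, which overlaps Elk4, may have fallen this way. Near Irf4, 37 Hist1 genes of 1 cluster rose together; they are argued against as the whole cause, since the adjusted p without Hist1 genes is 0.0372 (odds ratio 1.65). Strain differences carried with the targeted locus may account for the excess in these 3 deficiencies, but 91 of the genes belong to Irf4, where batch and genotype coincide. Fisher's test takes neighbouring genes as independent, which Hist1 genes and the interferon-inducible genes near Atf6 are not known to be. The excess depends on the window: 5 Mb adds Prdm1 (8 of 66, Fisher adjusted p = 0.0203) and finds fewer calls near Batf (4 of 105, adjusted p = 0.00666), and 20 Mb adds Stat3, Stat4 and Tbx21 (adjusted p = 0.0419, 0.0291 and 0.000414). An action of the missing factor on genes nearby was not tested.

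Cd4 stood at 391, 381 and 412 CPM in Batf, Bhlhe40 and Stat4 and at 1386 to 1669 CPM in the other 6 libraries of batches C and D. Libraries of A and B stood at 321 to 622 CPM. A different makeup of cell classes is argued against, since TFH-like cells of Bhlhe40 and Stat4 alone stood at no more than 344 CPM against at least 1389 CPM in the controls of C and D. A strain variant near the target is argued against for all 3 at once, since 2 of the 3 targets lie on other chromosomes than Cd4. Cd4 sequence carried by a CD4cre transgene in the other libraries is a candidate explanation that cannot be told apart from others. The CD4cre control of batch A had 1.18 times the Cd4 of the Prdm1flox control (448 CPM, against 1505 and 1669 in CD4cre controls 2 and 3, so the CD4cre label alone does not go with a high level), and the labels do not say which libraries carry the transgene.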

How the results depend on the processing

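Settings chosen after the data were seen are the counting term and what was run with it, shared barcodes, doublet scores, 1 spread in scaling, other seeds, no score limit, Irf4 centred on batch A and Hist1 genes left out. No paired analysis was possible because the labels tie libraries by batch and not 1 to 1; the batch term is the fit blocked by batch, and it could not be made for Irf4.

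The number of called genes depends on the model. With the counting term edgeR called 40, 2583, 2508, 10, 24, 5820, 806, 806, 1588, 12 and 129 for Atf6, Batf, Bcl6, Bhlhe40, Elk4, Irf4, Maf, Prdm1, Stat3, Stat4 and Tbx21 in all cells. In TFH-like cells it called 55, 60, 245, 59, 585, 41 and 175 for Atf6, Bhlhe40, Elk4, Prdm1, Stat3, Stat4 and Tbx21. In TR1-like cells it called 99, 1893, 649, 63, 69, 1324, 939, 97 and 607 for Atf6, Batf, Bcl6, Bhlhe40, Elk4, Maf, Stat3, Stat4 and Tbx21. Among controls set against the other 3 it called 133 and 133 for Prdm1flox control 1 and CD4cre control 1. The batch term, with 1 residual degree of freedom, gave 601, 34, 28, 3 and 1 for Batf, Bcl6, Maf, Prdm1 and Tbx21 in all cells and 0 for the other 5. TFH-like cells then gave 120, 132, 325, 189, 739, 126 and 427 for the same 7. TR1-like cells gave 186, 1929, 734, 149, 199, 1680, 910, 192 and 895 for the same 9. DESeq2 without the term called 20, 566, 380, 16, 15, 866, 299, 88, 177, 3 and 76 for the same 11 in all cells. Its TFH-like counts were 3, 9, 7, 9, 29, 6 and 15 for the same 7. Its TR1-like counts were 2, 175, 14, 4, 3, 75, 15, 1 and 38 for the same 9. Among controls it called 1, 133 and 111 for CD4cre control 3, Prdm1flox control 1 and CD4cre control 1. With the term it called 62, 1643, 41, 80, 55 and 287 for Atf6, Batf, Bhlhe40, Elk4, Stat4 and Tbx21 in all cells. TFH-like counts were 20, 14, 24, 12, 167, 19 and 28 for the same 7. TR1-like counts were 13, 419, 83, 14, 14, 242, 94, 16 and 108 for the same 9. No filter on low counts gave 24 and 34 for Batf and Irf4 in all cells, 1, 3, 1, 2 and 3 for Atf6, Bhlhe40, Elk4, Stat3 and Tbx21 in TFH-like cells and 1, 54, 6 and 4 for Atf6, Batf, Maf and Tbx21 in TR1-like cells. Against the 3 CD4cre controls alone, with fewer samples, edgeR called 0, 0 and 0 for Batf, Bcl6 and Irf4 in all cells and 0 and 0 for Batf and Maf in TR1-like cells. The stricter cell filter gave 8 for Batf, removal of shared barcodes 18 for Batf and removal of the highest doublet scores 0 for Bcl6. Where no cause is named here, the cause was not tested.

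With 1 control left out, which leaves 2 residual degrees of freedom, or 1 with the term, edgeR without the term called 0 (Batf), 0 (Bcl6) and 0 (Irf4) in all cells and 0 (Batf) and 0 (Maf) in TR1-like cells. With the term the counts ranged over 0 to 133 (Atf6), 406 to 3830 (Batf), 46 to 3864 (Bcl6), 0 to 169 (Bhlhe40), 0 to 451 (Elk4), 29 to 1999 (Maf), 3 to 1281 (Prdm1), 0 to 3095 (Stat3), 0 to 170 (Stat4) and 1 to 521 (Tbx21) in all cells. In TFH-like cells they ranged over 114 to 159 (Atf6), 129 to 222 (Bhlhe40), 319 to 656 (Elk4), 111 to 233 (Prdm1), 745 to 1099 (Stat3), 127 to 201 (Stat4) and 263 to 469 (Tbx21). In TR1-like cells they ranged over 179 to 244 (Atf6), 724 to 983 (Bcl6), 137 to 234 (Bhlhe40), 141 to 197 (Elk4) and 192 to 365 (Stat4).

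Of the genes named with the term, globins left out of the report included, 5 lost the call without CD4cre control 1, 90 without CD4cre control 2, 97 without CD4cre control 3, 5 without the Prdm1flox control, 33 with DESeq2 and, within classes, 16 of 69 with joint clustering, and none reversed under these. Without the term 117 gained a call with DESeq2, and adding the term gave 196 named genes a call by edgeR. Under Stat3 deficiency Il10 stood at -0.07 without the term, 1.14 with it, 1.11 with the batch term and 0.12 without the term against the CD4cre controls. Under Prdm1 deficiency Ccnb2 and Ube2c stood at -0.88 and -0.57 without the term, 2.71 and 2.60 with it or with the batch term, and Cenpf at 0.29, or -0.04 against the CD4cre controls. The globin Hba-a1 in TR1-like cells of Stat4 went from 3.35 without the term to -0.34 in jointly clustered cells. With 1 control left out the range was -0.04 to 0.84 for Cenpf under Prdm1, -0.94 to 0.22 for Ube2c under Prdm1 and -0.32 to 0.36 for Il10 under Stat3.

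Classes built from all libraries together turned the TFH-like share of Maf, from -17.01 to 40.55 percentage points against the control mean, and moved the TR1-like share to -5.12 and -7.52 for Atf6 and Prdm1. They left 20 TR1-like Batf cells, too few for the test of that class. With the term, TFH-like cells so defined gave 22, 19, 46, 13, 175, 13 and 44 for the same 7 as counts, and TR1-like cells 1031, 142, 172, 1724 and 333 for Bcl6, Bhlhe40, Elk4, Stat3 and Stat4, and without it TR1-like cells 0 for Maf. Only these classes allowed tests of TFH-like Maf cells, with 2423 calls (57 without the term), and TR1-like Prdm1 cells, with 1776 (0). Without centring the TFH-like difference was -28.72, -29.45, -28.18, -28.94, 19.87, -26.44 and 10.34 for Batf, Bcl6, Irf4, Maf, Prdm1, Stat3 and Tbx21, and the TR1-like one -6.53 and 3.8 for Atf6 and Tbx21. Naming without the score limit gave -30.69, -30.55, -30.36, -30.10, 16.98 and -26.93 for Batf, Bcl6, Irf4, Maf, Prdm1 and Stat3 (TFH-like), and seed 3 gave -32.42, -32.25, -32.28, -31.81, 19.78, -28.51 and 10.75 for Batf, Bcl6, Irf4, Maf, Prdm1, Stat3 and Tbx21. Seed 2 gave 9.17 for Stat4, and 1 spread in scaling 9.59 for Stat4 and, for TR1-like cells, -5.10 for Atf6. Set against controls of the same batch the TFH-like difference was -3.94, -26.17 and -5.02 for Atf6, Batf and Bhlhe40, and 12.07 and 8.61 for Prdm1 and Tbx21 instead of 4.79 and 1.34. With seed 1, doublets kept and Irf4 centred on batch A, 22, 33 and 2 results stayed on their side or within their spread.

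Camera with an estimated correlation called 0 lists and fry 0. Calls near the target passed Fisher's test with the term, at 4, 2 and 91 for Atf6, Elk4 and Irf4. With Hist1 genes left out, which was chosen after the calls were seen, it passed at 4, 2 and 54 for Atf6, Elk4 and Irf4. Without the term the calls were too few for a window to matter, and with it 20 Mb added Stat3, Stat4 and Tbx21 (adjusted p = 0.0419, 0.0291 and 0.000414). Depth limits the Irf4 library most, with 23.56 M UMIs over 2377 kept cells.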

Other observations

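All values here were chosen after the data were seen.

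Of the barcodes of the Batf library 997 also occurred in CD4cre control 2 and 110 in Stat3, against a median of 10 and at most 26 in the other 103 pairs of libraries. The shared barcodes had a median of 898 UMIs in Batf and 17502 in CD4cre control 2, with a correlation of 0.865 between the log UMI counts. They held 1.39% of the Batf UMIs (0.286% for those shared with Stat3).

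Ccnb2 and Ube2c, genes of dividing cells, stood at 0.317 to 0.697 and 0.772 to 0.936 CPM in the batch A controls and reached 15.9 and 21.1 CPM among all 4 controls. The share of cycling cells ran the other way, at 8.28% and 8.82% in the batch A controls and 1.89% and 2.25% in those of C and D. Cycling shares are therefore written beside controls of the same batch, while the grey band of the figure spans all 4 controls.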
